A study of Mus musculus with 2 samples.

How the data were processed

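H3K4me2 was measured by ChIP-seq in 2 biological replicates of mouse embryonic day 15.5 intestine, pools of 78 (replicate 1) and 62 embryos (replicate 2). The size range is 300 to 500 bp, per the labels. Reads were processed by the authors before deposit. Per the deposited notes that accompany the lists, peaks of each replicate were called from its filtered alignments against a control, a pooled list was called from both replicates with both controls, and a replicated list was derived from the other 3. The aligner, the peak caller, the rule for the replicated list and the read numbers are not given in the sources used here. The assembly is mm10, per the labels.

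Each deposited list gives, for every peak, its position, a signal value (taken as the authors' measure of enrichment, unit signal), a −log10 q-value and the offset of the summit. These are the authors' own values per peak and were used only to describe, rank or filter peaks within a list, and to compare the height of overlapping peaks between replicates. The deposited lists hold 58469 (replicate 1), 59263 (replicate 2), 61244 (pooled) and 42211 peaks (replicated). Peaks on other contigs (12 to 15 per list) were left out. Every replicated peak is also a line of the pooled list. Of the replicated peaks, 92.7% overlapped a peak in the own lists of both replicates, so the rest did not. A further 212 pooled peaks that overlapped peaks of both replicates are absent from the replicated list. The lists reach down to low −log10 q-values, and 4.23% of the peaks of replicate 1 and 3.45% of those of replicate 2 have a q above 0.05, so a stricter threshold was among the alternatives. A peak list shows where enrichment passed the authors' threshold: an absent peak is not shown to be absent mark, and with depth unknown no detection limit was computed.

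Coordinates were compared with GENCODE M21 on GRCm38 (the mm10 assembly) with 21853 protein-coding genes and 54361 TSSs on chromosomes 1 to 19, X and Y. Positions are printed 1-based. A gene was marked if a peak overlapped any of its protein-coding TSSs ± 1 kb by 1 bp or more. Peaks were joined into domains across gaps of up to 1 kb, and the widest domain overlapping a promoter window was the gene's domain. Peaks outside all windows were distal and were counted by summit within 50 kb of the 5′ end of the gene. Peaks that overlapped no promoter window were assigned to exon, intron or intergenic sequence by their summit. The CpG ratio was observed over expected CpG in 1 kb centred on the 5′ end of the gene, in 10 deciles. Gaps of at least 100 N were left out of the genome for random placement.

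Choices were fixed before the data were examined: the 18 gene lists, the 17 consensus words, the tests and the alternatives. All symbols of the lists were matched (Cblif as Gif). Genes were named by 4 rules: in each list the 4 marked members with the widest domain and the first 3 unmarked members in alphabetical order, the 20 widest domains, the 10 distal peaks with the highest signal value, and any Hox gene. Promoter marking was tested by two-sided Fisher's exact test against all other protein-coding genes, domain width and distal peaks by two-sided permutation tests (100000 random draws of genes), and words by McNemar's exact test (Fisher's exact test for the GC-matched control), each with Benjamini-Hochberg adjustment at 0.05 over the family. CpG-matched and density-matched tests used 10000 random lists. A ratio against a count of 0 used a floor of 3, and no ratio was given where both counts were at or below 3. Replicates were not compared by a test, since there were 2 libraries of 1 group.

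Alternatives were peaks of −log10 q of at least 5 or 10, each replicate's list alone, the pooled list, TSS windows of 500 bp and 2 kb, the 5′ end of the gene alone, autosomes only, other overlap rules, gaps of 0 and 3 kb, distances of 20 and 100 kb, matched backgrounds, a word window of 250 bp and a control 5 kb away. Added after the data were seen were control windows of the same GC content (bins of 2.5%, 5, 10 and 20 kb from distal summits), matching on the highest CpG ratio over all TSSs of a gene and, for domain width, counting each domain once in lists and background.

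The tests were checked on simulated data over 21853 genes in 40 runs. A list raised to 99% marked was called in 39 of 40 runs and a list lowered to 30% in 31. A list with domains raised 2.5-fold was called in 37 runs and one with distal peaks raised 2.5-fold in 34. Of 240 HNF4 words placed in random sequence 239 were found, which checks only the search for the word. Of unchanged lists, 6 of 600 were called for marking, 6 of 640 for width and 2 of 640 for distal peaks. The simulated genes were drawn independently, without dependence on CpG and without shared domains or peaks. These rates therefore do not cover lists of neighbouring genes, such as the Hox and receptor lists. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.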

Results

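H3K4me2, the dimethylated form of lysine 4 of histone H3 found at promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse intestine at embryonic day 15.5. The tissue came from strain B6NCrl, with the intestines of 78 embryos pooled in replicate 1 and those of 62 embryos pooled in replicate 2. The labels describe each pool as mixed in sex. There was 1 group of 2 biological replicates and no second condition, so the questions addressed were how far the pools shared peaks, where in the genome the mark lay, and which genes of the developing gut carried it. The peak lists hold no read counts, so the sequencing depth is unknown. Values given as mean ± SD are over the peak lists of the 2 replicates (n = 2), and tests over gene lists take genes, not animals, as their units.

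The pools of embryos shared their strong peaks, while many weak peaks were called in a single replicate. Replicate 1 had 58456 peaks and replicate 2 had 59248 on chromosomes 1 to 19, X and Y of mm10. Of a replicate's peaks, 75.7% ± 1.01 (SD, n = 2) overlapped a peak of the other by at least 1 bp. Each SD of a shared percentage is between both directions of the same comparison, so it does not measure variation between replicates. In replicate 1, 43826 peaks (75%) were shared and 14630 were not. In replicate 2, 45269 peaks (76.4%) were shared and 13979 were not. Shared peaks were wider, with a median of 764 bp in replicate 1 and 710 bp in replicate 2, against 237 bp and 223 bp for the peaks of a single replicate. Promoters held 44.9% and 45.0% of the shared peaks, and 8.80% and 8.88% of the unshared ones. Of the unshared peaks, only 78 in replicate 1 and 35 in replicate 2 had a −log10 q of at least 10. Across the 43826 shared peaks of replicate 1, the authors' signal values of the replicates had a Spearman rho of 0.841 and a Pearson r of 0.865 on the log2 scale. These correlations are across peaks, which are not independent replicates. With only peaks of −log10 q of at least 5 kept, 88.6% ± 3.31 (SD, n = 2) of peaks were shared. When the overlap had to cover at least 0.5 of the length of both peaks, the share was 58.5% ± 0.557 (SD, n = 2).

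**Figure D1:**
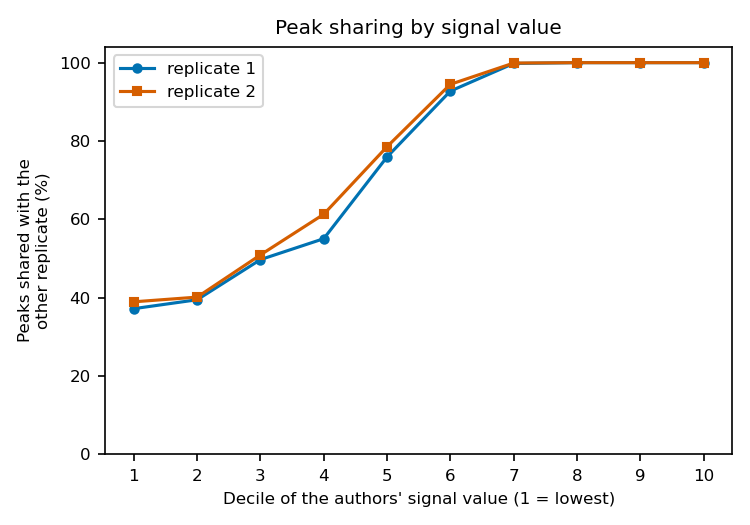
Share of a replicate's peaks that overlap a peak of the other replicate (vertical axis, percent) by decile of the authors' signal value within that replicate (horizontal axis, decile 1 lowest), with circles for replicate 1 and squares for replicate 2. The share rose from 37.2% and 38.9% in the lowest decile to 100% in deciles 8 to 10 of both replicates.

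The mark was concentrated at promoters. The authors' replicated list held 42199 peaks on chromosomes 1 to 19, X and Y, covering 54.5 Mb or 2.06% of the sequenced bases, and 43.4% of them overlapped a window of 1 kb on either side of a protein-coding transcription start site (TSS). Random placement of the same peaks within their chromosomes put 4.18% ± 0.0964 (SD over 1000 placements) there, and at most 4.48%, so the observed share was 10.4-fold higher. Introns held 25.9% of the replicated peaks against 36.2% by random placement, intergenic sequence held 26.8% against 57.2%, and exons outside promoters held 3.92% against 2.41%. Promoter peaks had a median width of 1802 bp, compared with 562 bp in introns and 627 bp between genes. In the lists of the single replicates the promoter share was lower, at 36.2% ± 0.456 (SD, n = 2), and among the 61231 pooled peaks it was 32.6%.

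Of 21853 protein-coding genes, 15022 (68.7%) had a replicated peak at a promoter, and the replicates' own lists gave 69.4% ± 0.0259 (SD, n = 2). The marked share followed the CpG content of the promoter, a property of its sequence. It was 7.32% in the decile of genes with the lowest ratio of observed to expected CpG and 99.4% in the highest decile.

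Mesenchyme, smooth muscle, signalling and epithelial genes were marked more often than other genes. The secretory and enteroendocrine list (72% marked) and the endothelial and mesothelial list (68.8%) did not pass the same test, and no list was tested against another. All 24 gut mesenchyme genes, all 17 smooth muscle and pacemaker genes and all 35 genes of Hedgehog, Notch, BMP, FGF and retinoid signalling were marked. So were 22 of 23 transcription factors of the gut epithelium and 23 of 25 epithelial and enterocyte genes. The exceptions among the transcription factors and the epithelial genes were Creb3l3, a regulator of lipid metabolism, and the brush-border disaccharidases Lct (lactase) and Sis (sucrase-isomaltase), which lacked a promoter peak in both replicates as well. Each of these 5 lists was marked more often than all other protein-coding genes (68.7% of all genes were marked) in a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 18 lists. By this Fisher test the adjusted p was 0.000724 for mesenchyme, 0.00472 for smooth muscle, 2.87e-05 for signalling, 0.00472 for the transcription factors and 0.0126 for the epithelial genes. The epithelial list was no longer past the threshold among peaks of −log10 q of at least 5 (Fisher's exact test, adjusted p = 0.0641), nor was smooth muscle at 10 (adjusted p = 0.337). Against random lists of the same promoter CpG deciles all 5 lists were still higher, the epithelial genes by the most, with 92% marked against 49.7% (permutation test, adjusted p = 0.0012, from the smallest p that 10000 random lists can give, 0.0002). With matching on the highest CpG ratio over all TSSs of a gene, added after the data were seen, the transcription factors (permutation test, adjusted p = 0.0540) and the signalling genes (adjusted p = 0.329) did not pass. All 35 signalling genes were marked, so no larger difference was possible for that list.

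Wnt pathway, Hox and housekeeping genes were also marked more often than other genes, but not past the threshold against genes of like promoter CpG. All 22 Wnt pathway and stem cell genes were marked (Fisher's exact test, adjusted p = 0.00101), among them Lgr4, Myc, Axin2 and Sp5. CpG-matched lists reached 91.3% (permutation test, adjusted p = 0.198). Of the Hox genes, 36 of 39 were marked (Fisher's exact test, adjusted p = 0.00194), against 91.1% of CpG-matched genes (permutation test, adjusted p = 1). All 20 housekeeping genes, such as Rpl13a, Actb, Ywhaz and Gapdh, were marked (Fisher's exact test, adjusted p = 0.00194), against 90.1% of CpG-matched genes (permutation test, adjusted p = 0.194). Every Wnt pathway and housekeeping gene was marked, so no larger difference was possible. For both lists the matched test therefore cannot decide whether promoter CpG accounts for the marking. In the enteric nervous system list, 20 of 23 genes were marked, including Zeb2, Hand2, Erbb3 and Ednrb, the endothelin receptor of migrating neural crest cells. Phox2b, Plp1 and Vip were not marked, and the list was not past the threshold (Fisher's exact test, adjusted p = 0.0913). Secretory and enteroendocrine genes were marked in 18 of 25 cases (Fisher's exact test, adjusted p = 0.880). The marked members included the secretory regulators Gfi1 and Atoh1 and the endocrine factors Insm1 and Pax6, and the unmarked ones included Gcg (proglucagon), Lyz1 (Paneth cell lysozyme) and Muc2 (goblet cell mucin). Endothelial and mesothelial genes were marked in 11 of 16 cases (Fisher's exact test, adjusted p = 1), Fli1, Wt1, Sox18 and Sox17 among them. Cdh5, Emcn and Lyve1 had no replicated peak at the promoter, although Emcn had one in replicate 2.

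Blood, liver and pancreas, and stomach, lung and thyroid genes were marked less often than other genes. Blood cell genes were marked in 7 of 19 cases (Fisher's exact test, adjusted p = 0.00739), with peaks at Runx1, Tal1, Ikzf1 and Klf1 and none at Adgre1, Aif1 and Ccr2. CpG-matched lists were marked at 36.5% (permutation test, adjusted p = 1). Liver and pancreas genes were marked in 6 of 19 cases (Fisher's exact test, adjusted p = 0.00194). The marked members included the transcription factors Mnx1, Pdx1 and Nkx6-1 and the transport protein gene Ttr. The genes Afp, Ahsg and Alb, which encode proteins secreted by the liver, had no replicated peak at the promoter, although Afp had one in replicate 1. Stomach, lung and thyroid genes were marked in 5 of 19 cases (Fisher's exact test, adjusted p = 0.000724). Foxj1, Nkx2-1, Foxe1 and Sox2 had a peak, and the gastric genes Atp4a, Atp4b and Gif (intrinsic factor) had none. Against CpG-matched lists, which were marked at 47.2% and 41.3%, neither list was past the threshold (permutation test, adjusted p = 0.236 for each). Heart and skeletal muscle genes were marked in 11 of 19 cases, with Ryr2, Myl7, Tbx20 and Pax3 marked and Ckm, Myf5 and Myh6 unmarked, and were not past the threshold (Fisher's exact test, adjusted p = 0.367). With TSS windows of 500 bp they were marked less often, by a difference of -31.3 percentage points (Fisher's exact test, adjusted p = 0.00774). Forebrain and midbrain genes were marked in 17 of 19 cases, Neurod6 and Otx2 being the unmarked ones. This was not past the threshold with the replicated peaks (Fisher's exact test, adjusted p = 0.0948), but it was with the peaks of replicate 1 alone (adjusted p = 0.0186) and replicate 2 alone (adjusted p = 0.0186), in each of which 18 of 19 were marked, Otx2 included. CpG-matched lists were marked at 88.2% (permutation test, adjusted p = 1).

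Germ cell genes and odorant receptors stood apart. Of 16 germ cell genes, only Dazl and Tdrd1 were marked (Fisher's exact test, adjusted p = 3.05e-05), with domains of 0.840 kb and 0.746 kb (Tdrd1 0.483 and 0.627 kb in the replicates), while Ddx4, Gdf9 and Acrv1 were among the 14 unmarked. CpG-matched random lists were marked at 65.6% (adjusted p = 0.0012, permutation test). Of 1465 olfactory and vomeronasal receptor genes, 6 were marked, among them Vmn1r4, Olfr56, Olfr94 and Olfr187, compared with 14.8% of CpG-matched genes (adjusted p = 0.0012, permutation test). For both lists the unadjusted p was 0.0002, the smallest that 10000 random lists can give. Olfr1, Olfr10 and Olfr1000 were unmarked. Receptor genes lie in arrays and are not independent of each other. Around the 5′ end, 953 of the 1465 had at least 90% unique words of 31 bases, against 14120 of the 15022 marked genes. Whether reads could be assigned uniquely to the other receptor promoters was not tested.

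**Figure D2:**
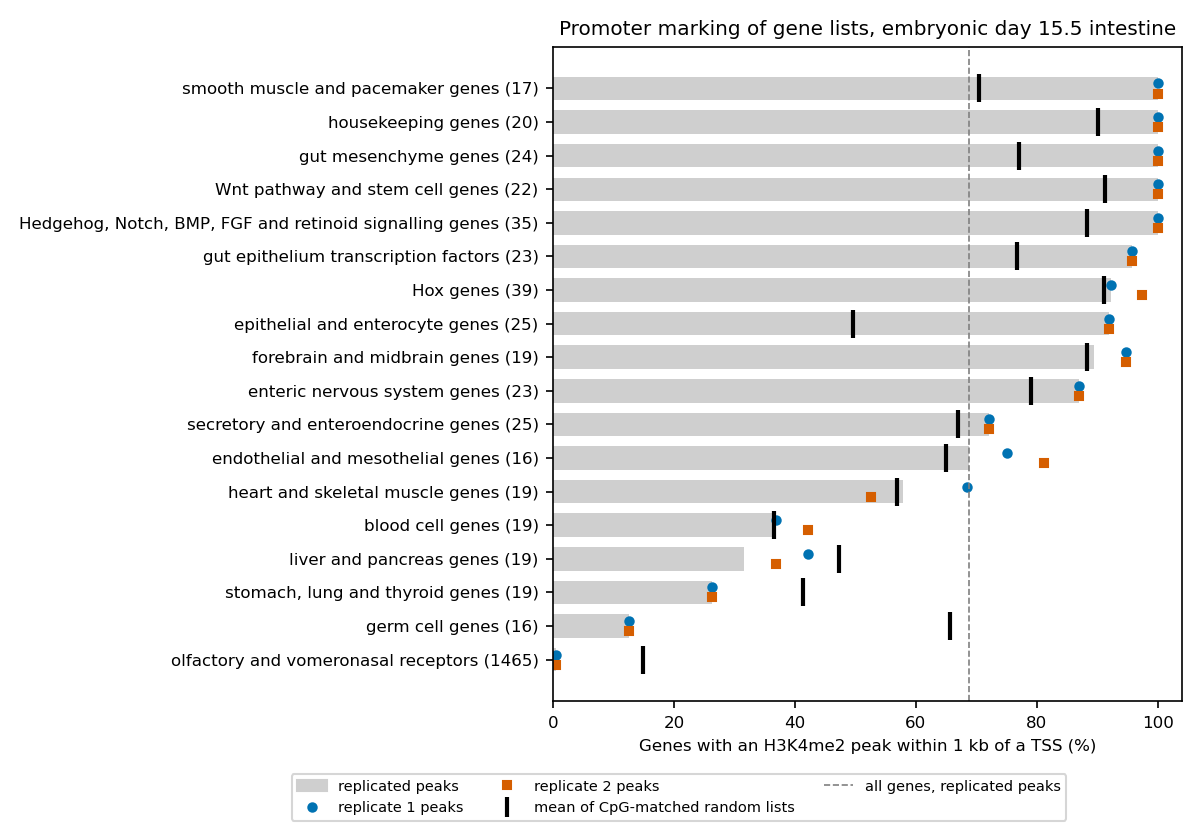
Share of genes with an H3K4me2 peak within 1 kb of a TSS (horizontal axis, percent) for the 18 gene lists, with the number of genes in parentheses. Bars are the replicated peaks, circles and squares the peak lists of replicates 1 and 2, black ticks the mean of 10000 random lists matched on promoter CpG, and the dashed line all protein-coding genes (68.7%); germ cell genes stood at 12.5% against a matched mean of 65.6%.

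Promoter domains were wider over mesenchyme, signalling, epithelial and Hox genes than over other marked genes. Peaks no more than 1 kb apart were joined, and the median domain over all marked promoters was 2541 bp wide. In a two-sided permutation test with 100000 random draws of marked genes, domains were wider over Hox genes (median 7.27 kb, 2.86-fold), gut mesenchyme genes (6.70 kb, 2.64-fold), signalling genes (6.69 kb, 2.63-fold), epithelial transcription factors (5.95 kb, 2.34-fold) and epithelial and enterocyte genes (4.72 kb, 1.86-fold). Each of these 5 had an adjusted p of 6.8e-05, from an unadjusted 2e-05 that is the smallest the draws can give. Neighbouring Hox genes share domains, and the 36 marked ones lay in 26. With each domain counted once in lists and background, a test added after the data were seen, the Hox median was 4.36 kb (1.76-fold, permutation test, adjusted p = 6.8e-05), below those of mesenchyme (2.71-fold), signalling (2.71-fold) and both epithelial lists (2.40-fold and 1.91-fold). In the same permutation test smooth muscle genes (4.28 kb, adjusted p = 0.000977), housekeeping genes (3.98 kb, adjusted p = 0.00151) and Wnt pathway genes (3.54 kb, adjusted p = 0.0115) were also wider. Domains were narrower over secretory and enteroendocrine genes (1.44 kb, adjusted p = 0.000389), heart and skeletal muscle genes (1.07 kb, adjusted p = 0.00034) and the 6 marked receptor genes (1.05 kb, adjusted p = 0.00292, permutation test). By permutation the medians of the enteric nervous system (2.78 kb, adjusted p = 0.553), endothelial (2.03 kb, adjusted p = 0.267), blood (2.07 kb, adjusted p = 0.431), forebrain (2.60 kb, adjusted p = 0.886), liver and pancreas (2.40 kb, adjusted p = 0.806) and stomach, lung and thyroid lists (3.05 kb, adjusted p = 0.553) did not pass, and the germ cell list had too few marked genes to test. The epithelial and enterocyte result rested on the joining of nearby peaks: with touching peaks only, its ratio was 0.988 (permutation test, adjusted p = 0.979), that of smooth muscle 1.08 (adjusted p = 0.837) and that of housekeeping genes 1.29 (adjusted p = 0.0686). With gaps of 3 kb joined, the secretory list no longer passed (permutation test, adjusted p = 0.0813), and the enteric nervous system (1.51-fold, adjusted p = 0.0186) and forebrain lists (1.73-fold, adjusted p = 0.00826) were wider.

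The widest domain spanned Hoxb3 to Hoxb6 on chromosome 11, 96290746 to 96346779 (56.0 kb). It was followed by the domain of Ptch1, the Hedgehog receptor, on chromosome 13, 63548300 to 63574055 (25.8 kb). The replicates' domains at Ptch1 were 24.0 ± 2.93 kb wide (SD, n = 2). Foxf1, a transcription factor of the visceral mesoderm, had a domain on chromosome 8, 121071197 to 121093083 (21.9 kb; 21.7 ± 0.272 kb, SD, n = 2). Nr2f2, an orphan nuclear receptor of mesenchyme and vessels, had one of 25 kb on chromosome 7, 70345832 to 70370873. The homeobox genes Meis2 (21.5 kb) and Meis1 (16.7 kb), the T-box gene Tbx2 (16.1 kb), Foxf2 (15.7 kb) and Nr5a2 (15.1 kb) also ranked among the 20 widest. So did the domain over Mamdc4, Phpt1 and Ajm1 (17.8 kb), one over a run of genes that includes Mvp, Maz and Kif22 (15.5 kb), 3 domains of the Hoxa cluster, and those of Bahcc1, Lasp1, Zfp503, Zmynd8, Rhof with Setd1b, and Nfib. In the replicated list, the widest domains of the epithelial transcription factors lay over Gata4 (14.2 kb; 17.1 ± 4.18 kb, SD, n = 2), Prdm1 (13.2 kb), Gata6 (12.4 kb) and Sox9 (9.08 kb). The order differed in the replicates' own lists, where Foxa1, named after its values were seen, had 16.5 ± 0.117 kb (SD, n = 2), against 5.77 kb in the replicated list. Of the epithelial and enterocyte genes, Anpep, Krt8, Cgn and Krt19 (6.96 to 7.97 kb) had the widest replicated domains. Smad7 (13.5 kb), Shh (10.5 kb) and Wnt5a (9.59 kb) followed Ptch1 in the signalling list. Etv1, Tpm2, Srf and Smtn led the smooth muscle list at 5.11 to 6.88 kb with the replicated peaks. In the replicates' own lists the order within the lists varied: Etv1 had 6.75 kb in replicate 1 and 4.57 kb in replicate 2, and Smad7 14.3 and 9.91 kb. Genes named after their values were seen also led there, such as Mylk (6.82 kb, replicate 1) in the smooth muscle list and Cdh17 (8.5 kb, replicate 1) in that of the enterocyte genes. In the enteric nervous system list, Zeb2 (13.2 kb) and Hand2 (12.5 kb) were widest.

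Distal peaks, those outside every promoter window, were most numerous around Hox, epithelial, signalling and mesenchyme genes. There were 23904 distal replicated peaks, and a gene had on average 1.7 of them within 50 kb of its TSS. A peak outside the windows could be joined into a promoter domain and still count as distal. Domain width and distal counts are therefore not separate measures. Of the distal peaks, 1644 (6.88%) lay at promoters of the 10862 long noncoding RNA genes whose promoters lie away from every protein-coding promoter window. Distal peaks at the rest of the 13374 long noncoding RNA genes were not counted, so the full share may be higher. Hox genes had 11.9 (7-fold), epithelial and enterocyte genes 5.72 (3.36-fold), epithelial transcription factors 5.57 (3.27-fold), signalling genes 4.46 (2.62-fold), mesenchyme genes 4.04 (2.37-fold) and forebrain and midbrain genes 3.63 (2.14-fold). In a two-sided permutation test with 100000 draws the adjusted p was 7.2e-05 for the first 4, with the unadjusted p at 2e-05, the smallest the draws can give, 0.0003 for mesenchyme and 0.00509 for the forebrain list. Hox genes lie within 50 kb of each other and share distal peaks, so they are not independent. Some genes of the other lists also lie that close, such as Krt8 and Krt18 or Pdx1 and the epithelial factor Cdx2. Krt18 and Cdx2 are named here for their position, and the counts of such neighbours can include the same peaks. The receptor genes had 0.122 (permutation test, adjusted p = 7.2e-05). Around single genes there were 17 distal peaks near Krt8, 15 near Gata4, 15 near Pdx1, 11 near Smad7 and 9 near Krt19, and the replicates' own lists held more, for example 28 and 27 near Gata4. The lists of the replicates alone held more distal peaks, at 8.68 ± 0.170 (SD, n = 2) for the epithelial genes and 8.98 ± 0.707 (SD, n = 2) for the epithelial transcription factors. In the permutation test Wnt pathway (2.82, adjusted p = 0.0743), housekeeping (2.85, adjusted p = 0.0743), liver and pancreas (2.95, adjusted p = 0.0729) and smooth muscle genes (2.71, adjusted p = 0.155) did not pass. Wnt pathway genes did pass with the list of replicate 2 alone (1.84-fold, permutation test, adjusted p = 0.0157) and of replicate 1 alone (1.94-fold, adjusted p = 0.00589), and housekeeping genes with that of replicate 1 alone (2.01-fold, adjusted p = 0.00589). The enteric nervous system (2.30, adjusted p = 0.332), endothelial (2.38, adjusted p = 0.357), heart and skeletal muscle (2.05, adjusted p = 0.634), secretory (1.80, adjusted p = 0.925), stomach, lung and thyroid (1.74, adjusted p = 0.927), germ cell (1.56, adjusted p = 0.927) and blood lists (1.53, adjusted p = 0.925) were not past the threshold of the permutation test.

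**Figure D3:**
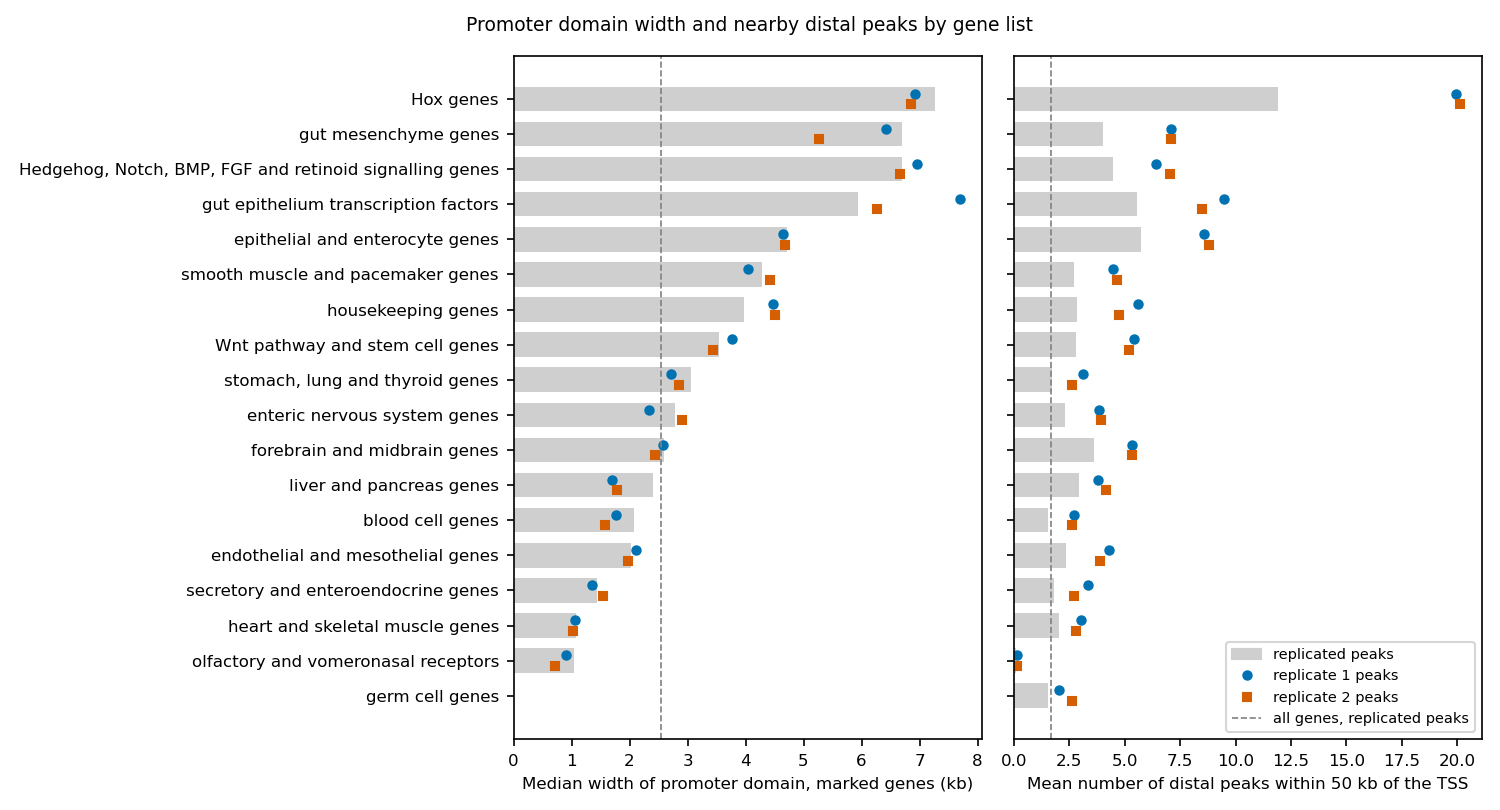
Left, median width of the H3K4me2 domain over the promoters of marked genes (horizontal axis, kb); right, mean number of distal peaks within 50 kb of the TSS, for the 18 gene lists. Bars are the replicated peaks, circles and squares the lists of replicates 1 and 2, and dashed lines all genes (2541 bp and 1.7 peaks); the germ cell list has no width because only 2 of its genes were marked.

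The 10 distal replicated peaks with the highest signal value lay within genes in 6 cases and between genes in 4. The highest, at 59.5 (52.3 and 52.1 in the replicates), overlapped coding sequence of Klhl31 on chromosome 9, 77654891 to 77656196. The next lay in an intron of Cdh23 on chromosome 10, 60685928 to 60688144 (55.7), in coding sequence of Prrt4 on chromosome 6, 29169502 to 29171733 (55.4), and in coding sequence of Pitx3 on chromosome 19, 46135395 to 46137693 (55). Intergenic peaks of this group were nearest to Phf21a, Gm17304, Cxxc5 and Hmga2, at 33.4 to 76.2 kb from the TSS, and the rest lay in Hapln2 and in an untranslated region of Prr7.

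The 4 Hox clusters, whose genes carry positional identity along the gut, differed in how much of their length was marked. Peaks covered 77.5% of the Hoxa cluster (chromosome 6, 52155590 to 52260880), 46.5% of Hoxb (chromosome 11, 96194316 to 96368256), 41.8% of Hoxd (chromosome 2, 74668310 to 74765142) and 31.3% of Hoxc (chromosome 15, 102921103 to 103036852). The replicates' own lists gave 70.6% ± 0.236, 43.6% ± 0.323, 35.5% ± 1.75 and 29.7% ± 0.180 (SD, n = 2), so the clusters differed by more than the replicates did. The Hoxb span includes a stretch without replicated peaks, between 96194641 and 96250890, so its difference from Hoxa depends on the span taken. Near the 5′ ends (2 kb on either side) of Hoxb2 to Hoxb9, coverage was 81.2 to 100%. Of 39 Hox genes, 36 had a marked promoter. The promoter of Hoxc12 was unmarked in the replicated list and in both replicates, and those of Hoxc11 and Hoxd12 had a peak only in replicate 2 (0.190 kb and 0.185 kb wide). Within 2 kb of the 5′ end of the gene, Hoxa2, Hoxa5, Hoxb3 and Hoxb4 were covered over 100% of the window, whereas coverage was 55.1% at Hoxa13, 28.9% at Hoxb13, 23.3% at Hoxc13 and 30.7% at Hoxd13. Low coverage was also found at genes of low number, such as Hoxc4 (27.9%) and Hoxb1 (33.4%), and high coverage at Hoxa11 (83.4%). The replicates' own lists gave 16.6% ± 2.28, 35% ± 2.79 and 65.6% ± 0.672 (SD, n = 2) at these 3 genes. The window lay only at the annotated 5′ end, so low coverage there does not show low coverage at other TSSs of a gene. For example, a replicated peak (chromosome 15, 103033884 to 103037428) lay over the end of the Hoxc cluster at 103036852, outside the window of Hoxc4.

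**Figure D4:**
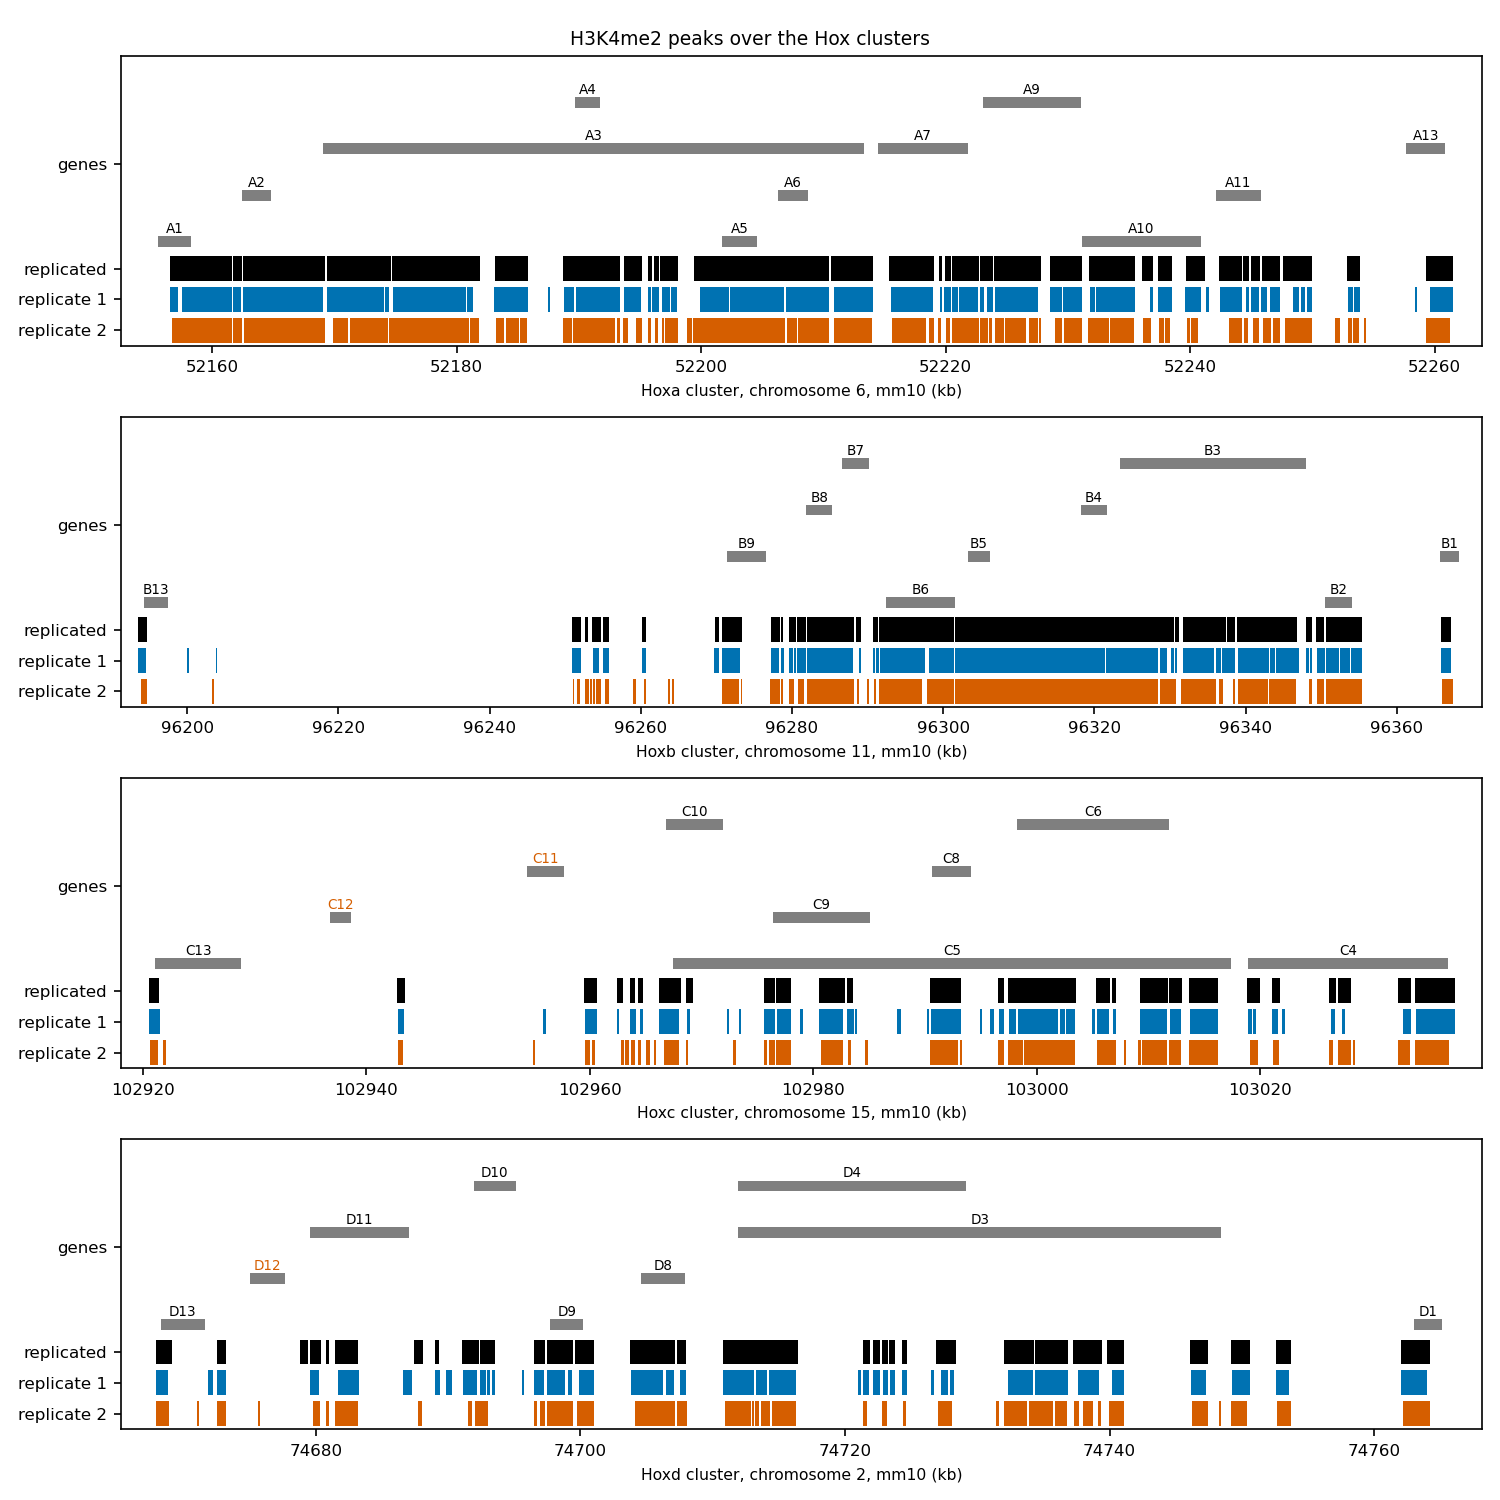
H3K4me2 peaks (filled bars) of the replicated list and of replicates 1 and 2 over the 4 Hox clusters, with annotated genes in gray (horizontal axis, mm10 position in kb); labels in orange mark the genes without a replicated peak at the promoter. The widest joined domain (56.0 kb) lay over Hoxb3 to Hoxb6, and the promoters of Hoxc11, Hoxc12 and Hoxd12 had no replicated peak.

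Binding words of transcription factors of the gut were counted within 100 bp of the summits of the 23904 distal peaks and compared with the same word reversed. The HNF4 word (CAAAGKYCA) was in 375 peaks against 150 for its reversed form (2.5-fold), the GATA word (AGATAAG) in 596 against 285 (2.09-fold), the TEAD word (ACATTCCW) in 500 against 212 (2.36-fold) and the CDX word (TTTATKRC) in 528 against 365 (1.45-fold). Words for FOXF (1.38-fold), MEF2 (2.36-fold) and NEUROD (2.53-fold) were also more frequent. In McNemar's exact test with Benjamini-Hochberg adjustment over 17 words, the adjusted p was 8.25e-23 for HNF4, 7.84e-26 for GATA, 2.38e-27 for TEAD, 7.04e-08 for CDX, 1.12e-17 for FOXF, 3.29e-05 for MEF2 and 2.15e-37 for NEUROD. By McNemar's exact test the FOXA word was not past the threshold (1.08-fold, adjusted p = 0.170), and the SOX word was less frequent than its reversed form (0.901-fold, adjusted p = 0.0273). Every match of the FOXA word (TGTTTAC) is, on the other strand, also a match of the FOXF word (RTAAACA). The 777 peaks with FOXA are therefore among the 1591 with FOXF, and these words do not tell the factors apart. In the same exact test the KLF (1.06-fold, adjusted p = 2.56e-06), AP1 (1.12-fold, adjusted p = 0.0273) and CRX and OTX words (1.41-fold, adjusted p = 0.0255) also passed, the SRF (1.12-fold, adjusted p = 0.372) and PHOX2 words (0.6-fold, adjusted p = 0.483) did not, and HNF1 was found in 3 peaks against 1. The CTCF word occurred in 37 peaks and its reversed form in 0, at least 12.3-fold higher over all peaks against a floor of 3 (73 against 3, 24.3-fold, in replicate 1 alone and 73 against 1 in replicate 2 alone), and the E-box word in 410 against 14 (29.3-fold), but the reversed forms of both, and those of HNF4 and CDX, hold or can hold CpG, which the words do not. With the list of a single replicate, the SRF word passed (1.21-fold in replicate 1 and 1.23-fold in replicate 2), while SOX did not pass in replicate 1 (0.939-fold) nor CRX and OTX in replicate 2 (1.17-fold). The directions depended on the control. The controls that follow were taken only within 100 bp of the summits, so their calls are not shown to hold in wider windows. Against unmarked sequence 5 kb away (McNemar's exact test), KLF (2.44-fold, adjusted p = 3.68e-258), E-box (1.52-fold, adjusted p = 8.12e-07) and FOXA words (1.31-fold, adjusted p = 2.77e-06) were more frequent in the peaks. CDX (0.813-fold), FOXF (0.908-fold), NEUROD (0.780-fold), AP1 (0.885-fold) and PHOX2 (0.222-fold) were less frequent by this exact test, with adjusted p of 0.00115, 0.0109, 1.58e-05, 0.0249 and 0.0011. The other words were not past the threshold, among them GATA (0.886-fold, exact test, adjusted p = 0.0589), HNF4 (1.17-fold, adjusted p = 0.0699) and TEAD (1.07-fold, adjusted p = 0.392). Against unmarked windows of the same GC content, a control added after the data were seen, 9 words were more frequent by Fisher's exact test. These were CDX (1.86-fold), MEF2 (1.80-fold), FOXA (1.74-fold), FOXF (1.67-fold), E-box (1.43-fold), GATA (1.34-fold), HNF4 (1.34-fold), KLF (1.21-fold) and TEAD (1.18-fold), with adjusted p from 3.16e-37 for FOXF to 0.0234 for TEAD in Fisher's exact test. FOXA and FOXF share matches and are not separate results. NEUROD (0.855-fold, Fisher's exact test, adjusted p = 0.0101) and AP1 (0.896-fold, adjusted p = 0.0462) were less frequent, and the other words were not past the threshold.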

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

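The counts below were chosen after the peak lists were seen and concern peaks or promoters that the comparisons of the report did not take up as such. In the pooled list, 5399 peaks overlapped no peak of either replicate, so they were called only when the replicates were combined. Whether they reflect signal or background was not tested. The replicated list also had 12 peaks on unplaced or unlocalised contigs. At promoters of long noncoding RNA genes that lie away from every protein-coding promoter window, 1572 of 10862 genes (14.5%) had a replicated peak, and these are described below under other observations.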

How the results depend on the processing

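The GC-matched control for words, the matching on the highest CpG ratio and the count of each domain once were tests chosen only after the results were seen. Of 595 values under alternatives for 77 results, 471 were as reported in direction and side of the threshold or within the spread of the replicates, 26 were no longer past the threshold, 24 newly passed it, 38 moved by more than the spread and 36 changed direction. For peak sharing, the spread was that between both directions of the same comparison, which does not measure variation between replicates. Where a value below changed a call or a direction, the cause was not tested. Depth is unknown, so what it limits was not assessed, and no paired analysis was possible because only 1 group was measured.

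Peak sharing between replicates was 67.8% when 0.5 of a peak's own length had to overlap, 58.5% when 0.5 of both had to, 88.6% at a −log10 q of at least 5 and 93.7% at 10. Spearman's rho was 0.931 for peaks overlapping by 0.5 of both. The promoter share of peaks was 46.8% and 57.1% at those thresholds, 32.6% in the pooled list, 41.4% and 48% with windows of 500 bp and 2 kb, 37% with the 5′ end of the gene alone, 42.8% on autosomes and 35.9 to 36.5% with a replicate left out. The share of marked genes was 68.4% and 67.3% at the thresholds, 69.9% in the pooled list, 68.1% and 69.7% with the windows, 65.9% with the 5′ end alone and 69.3 to 69.4% with a replicate left out. Coverage of the Hox clusters at a −log10 q of at least 5 was Hoxa (77.2), Hoxb (44.7), Hoxc (28.2) and Hoxd (39.4) percent. In the pooled list it was Hoxa (80.0), Hoxb (47.7), Hoxc (36.3) and Hoxd (45.1), and with a replicate left out Hoxa (70.5 to 70.8), Hoxb (43.4 to 43.8), Hoxc (29.5 to 29.8) and Hoxd (34.2 to 36.7).

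Promoter marking is given as the difference in percentage points from the background. Lists marked in full with the replicated peaks, such as the Wnt pathway, signalling and housekeeping lists, could show no larger difference from a matched background. At a −log10 q of at least 5, it was no longer past the threshold for epithelial genes (19.6) and changed direction for secretory genes (-0.417) and endothelial genes (-5.92). At 10, it was no longer past the threshold for epithelial genes (4.75) and smooth muscle genes (15.1) and changed direction for secretory genes (-11.3) and endothelial genes (-4.76). With windows of 500 bp, it changed direction for endothelial genes (-5.65) and newly passed for heart and skeletal muscle genes (-31.3). For forebrain genes it newly passed with the pooled list (24.9), the 5′ end alone (23.6) and a replicate left out (25.4 to 25.4). Against CpG-matched lists, it was no longer past the threshold for Wnt pathway genes (8.67), Hox genes (1.19), liver and pancreas genes (-15.6), stomach, lung and thyroid genes (-15) and housekeeping genes (9.91), and changed direction for blood cell genes (0.383) and heart and skeletal muscle genes (1.08). Against lists matched on the highest CpG ratio, it was no longer past the threshold for epithelial transcription factors (14.7), Wnt pathway genes (7.46), signalling genes (5.6), liver and pancreas genes (-13.1), stomach, lung and thyroid genes (-8.9) and housekeeping genes (2.29), and changed direction for blood cell genes (3.82), Hox genes (-0.438), forebrain genes (-1.79) and heart and skeletal muscle genes (2.8).

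Domain width is given as the ratio to random marked genes. With touching peaks only, it changed direction for epithelial genes (0.988) and forebrain genes (0.995) and was no longer past the threshold for smooth muscle genes (1.08) and housekeeping genes (1.29). With gaps of 3 kb joined, it was no longer past the threshold for secretory genes (0.765), newly passed for enteric nervous system genes (1.51) and forebrain genes (1.73) and changed direction for liver and pancreas genes (1.18). It also changed direction for forebrain genes (0.987) with the pooled list, and with a replicate left out it ranged across 1 for enteric nervous system genes (0.943 to 1.17) and forebrain genes (0.988 to 1.04). With each domain counted once, no list changed its side of the threshold or its direction, although the ratio of Hox genes was 1.76 against 2.86 with every gene counted.

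Distal peaks are given as the ratio to random genes. The ratio newly passed at a −log10 q of at least 5 for Wnt pathway genes (1.79) and housekeeping genes (1.79), with the pooled list for Wnt pathway genes (2.05), within 20 kb for enteric nervous system genes (2.09), within 100 kb for housekeeping genes (1.69) and against lists of like gene density for Wnt pathway genes (2.00) and liver and pancreas genes (1.89). Within 100 kb it changed direction for blood cell genes (1.01). With a replicate left out, the ratios that changed were those of secretory genes (0.966 to 1.2), Wnt pathway genes (1.84 to 1.94), heart and skeletal muscle genes (0.99 to 1.09), stomach, lung and thyroid genes (0.934 to 1.11) and housekeeping genes (1.69 to 2.01).

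Words are given as the ratio to the control. At a −log10 q of at least 5, those no longer past the threshold were AP1 (1.11) and CRX and OTX (1.38). In windows of 250 bp, FOXA (1.14) and SRF (1.15) newly passed. The CTCF word was in 727 peaks against 5 for its reversed form in these windows (145-fold), compared with 37 against 0 within 100 bp. Its count thus depended strongly on the window. Its reversed form holds CpG, which bears on the ratio and not on the count of the word itself. The controls 5 kb away and of the same GC content were run only within 100 bp. Their calls are therefore not shown to hold in the wider windows. Against sequence 5 kb away, HNF4 (1.17), TEAD (1.07), CTCF (1.68), MEF2 (1) and CRX and OTX (1.18) were no longer past the threshold, FOXA (1.31) and PHOX2 (0.222) newly passed and CDX (0.813), GATA (0.886), FOXF (0.908), SOX (1.02), AP1 (0.885), SRF (0.811) and NEUROD (0.78) changed direction. Against GC-matched windows, FOXA (1.74) newly passed and SOX (1.06), AP1 (0.896), CTCF (0.857), NEUROD (0.855) and CRX and OTX (0.936) changed direction. With a replicate left out, the words that changed were SRF (1.21 to 1.23), CRX and OTX (1.17 to 1.29), PHOX2 (1.2 to 1.22), FOXA (0.998 to 1.05) and SOX (0.878 to 0.939), and the CTCF ratio, 12.3 against a floor, was 24.3 in replicate 1 and 73 in replicate 2. The HNF1 word was too rare for a ratio under every control with replicated peaks within 100 bp, but within 250 bp it was in 45 peaks against 4 for its reversed form.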

Other observations

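The tests of Hox paralogue groups, of CpG-rich unmarked genes, of CpG content and of brain cells were chosen only after the results were seen, as were the genes named here. The CpG-matched comparison that serves for CpG content was itself fixed beforehand; only its use to weigh an explanation came later.

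Some long noncoding RNA genes lay under broad domains, although the widths of this class were not tested against those of other genes. Of the 1572 marked genes whose promoters lie away from protein-coding ones, 1446 had a domain that touched no protein-coding promoter window. The widest of these lay over Carmn, a smooth muscle and cardiac RNA that hosts a pair of microRNAs, on chromosome 18, 61647455 to 61666791 (19.3 kb). Others lay over Dleu2 (9.98 kb), Malat1 (9.70 kb), Neat1 (9.34 kb) and the imprinted gene H19 (9.07 kb), each with a promoter peak in both replicates.

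Along the Hox clusters, coverage within 2 kb of the 5′ end was higher for paralogue groups 1 to 9 (79.4% ± 20.1, SD over 27 genes) than for groups 10 to 13 (36.2% ± 26, SD over 12 genes). A permutation of the groups within clusters (100000 draws, two-sided) gave a p of 2e-05 for this difference of 43.2 percentage points, and the replicates' own lists gave 43.6 and 46.0 points. Neighbouring Hox genes share peaks, so the genes are not independent. Hoxd3 and Hoxd4, for example, had coverage of 78.1% and 78.2%. Each gene was represented only by its annotated 5′ end, not by its other TSSs.

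Chromosome Y held almost no peaks although the labels call both pools mixed in sex, and how the authors aligned or filtered reads of this chromosome is not given in the sources used here, so the few peaks are not shown to reflect the mark. There were 2 replicated peaks on it, and 0 of its 183 protein-coding genes had a marked promoter in the replicated list. Among the 5 with at least 90% unique sequence around the 5′ end (Eif2s3y, Uty, Ddx3y, Usp9y and Sry), only Uty had a promoter peak, in replicate 2 alone, with a signal value of 2.68. The CpG ratios of Eif2s3y (0.767), Uty (0.751) and Ddx3y (0.835) lie in deciles 8 and 9 of all genes, of which 98.9% and 99.2% were marked.

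Of the 16 germ cell promoters, 14 had no replicated peak, which does not show that they lacked the mark. The marked share differed from that of CpG-matched lists by -53.1 percentage points, which argues against low CpG content as the cause for the list as a whole. It does not speak for single members of low CpG ratio, such as Acrv1 (0.0233), since only 7.32% of genes in the lowest decile were marked. The median share of unique 31-base words around the 14 unmarked promoters was 100%, and at least 90% at each, which argues against a lack of uniquely assigned reads. Of the 7 germ cell genes with a CpG ratio of at least 0.6, 5 were unmarked (Ddx4, Gdf9, Mael, Sycp1 and Sycp3), whereas 171 of all 10041 such genes were (Fisher's exact test, p = 2.76e-08). No biological explanation was tested, since the design has 1 group.

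Promoter peaks at forebrain and midbrain genes may follow from CpG-rich promoters, since the marked share differed by 1.25 percentage points from that of CpG-matched lists. Brain cells in the dissected tissue cannot be told apart from this by promoter peaks, since only 4 members have a CpG ratio under 0.5. Of these, 3 (75%) were marked (Foxg1, Neurod2 and Tbr1), against 35.3% of all other such genes (Fisher's exact test, p = 0.129). The excess of distal peaks near this list stays open, and no biological explanation was tested.

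The excess of words over their reversed forms was weighed against word frequency (the same ratio 5 kb away). The words alone were also compared with windows of the same GC content. In peaks, the ratio of word to reversed word was 1.77 (GATA), 1.38 (TEAD), 1.21 (HNF4), 1.21 (NEUROD) and 1.16 times (CDX) that 5 kb away, but none of these words was itself past the threshold as more frequent than 5 kb away (GATA 0.886-fold, TEAD 1.07, HNF4 1.17, NEUROD 0.780 and CDX 0.813). GATA and TEAD met the bound set beforehand on this ratio (Fisher's exact test, p = 5.45e-10 and 0.00519), but the reversed word fell, from 559 windows 5 kb away to 280 peaks for GATA and from 272 to 211 for TEAD, whose own word was in 492 peaks against 461 windows. The ratio was therefore read only where the word itself was more frequent, a requirement added after the values were seen, and word frequency stays open for all 5, CDX included, whose ratio was under the bound. A word and its reversed form hold the same bases, so the GC-matched windows cannot weigh the excess of one over the other. They show only that CDX (1.86-fold), GATA (1.34-fold), HNF4 (1.34-fold) and TEAD words (1.18-fold) were more frequent in peaks than in such windows. The NEUROD word was less frequent there (0.855-fold). Binding was not measured.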
